A study of Mus musculus with 2 samples.

How the data were processed

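Sorted cells of mouse embryos (C57BL/6J) were profiled with droplet-based 3′ single-cell RNA sequencing (version 3 chemistry) in 1 control and 1 mutant library. Per the submitters' processing notes, Cell Ranger (no version given) and genome build mm10 were used; the annotation release, the filter on cells and the counting settings are not given in the sources used here. The deposited matrix holds raw UMI counts of 27998 genes in 9917 cells, per the file headers. The deposited cell table gives the genotype word of each cell, its total count, its number of detected genes, its mitochondrial fraction and a size factor. The deposited mitochondrial fraction equals the share of UMIs on mitochondrially encoded genes, recomputed from the matrix. The deposited size factor is a ratio, the total of a cell divided by 1 constant, and was not used. All 3 deposited tables were read, and cells were put in groups by the genotype word. No cell-type annotation was used here. The lowest total of a cell was 501 UMIs in both libraries.

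Cells of both libraries were clustered together without batch correction, since the library is the group. Counts of 2000 variable genes, leaving out mitochondrial, ribosomal-protein, hemoglobin and sex-linked genes, were reduced to 30 principal components; a graph of 20 neighbours with at least 3 shared neighbours was partitioned with the Leiden method (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0) at resolution 1, with 0.5 and 1.5 as alternatives. Clusters were named from markers fixed before the data were examined. A cluster was endothelial-like where its endothelial marker level reached 1/2 of the level of the median cluster and no other class led among its 10 leading genes. A cluster led by another class took that name only below this bound. The bound was set after seeing the data, since a bound of 1/3, tried first, left the hematopoietic cluster 15 (level 0.368) without a name. Clusters 13 and 15 were kept out of the endothelial-like class by their leading genes, not by the bound. Cluster 9, of shallow cells without a marker among its 10 leading genes (249 control and 135 mutant cells, 3.73% and 4.16%), and cluster 14, with endothelial markers but leading genes of smooth muscle (0 control and 213 mutant cells, 6.57% of the mutant), stayed unnamed. No doublet caller was run and no doublets were removed; leaving out the deepest 1% of cells per library (67 control and 33 mutant cells) served as an alternative. Free RNA was not removed: hemoglobin genes, which sorted endothelium should lack, took 2511 CPM in the control and 1312 CPM in the mutant.

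Raw UMI counts were summed per class and library and divided by the class total to give CPM. The endothelial-like class held 56393658 control and 19459463 mutant UMIs, so a count of 0 allows 0.0532 and 0.154 CPM, from a floor of 3 UMIs. Levels have exact Poisson, ratios exact conditional binomial and shares exact Clopper-Pearson intervals at 95% (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). Log2 ratios had 0.5 UMI added to both sums. Ratios were made for classes with at least 50 cells in each library and genes with at least 20 UMIs over both. A gene list was summarised by the median log2 ratio of members with a mean of at least 5 CPM and placed among 10000 random lists of its size, matched in 20 bins of mean expression. Since each group had 1 library, no p-value was computed. The genes to be named were fixed before the data were examined: in endothelial-like cells the 12 higher and 12 lower ones by the interval bound nearest to 1, among those with a mean of at least 20 CPM and outside the mitochondrial, ribosomal, hemoglobin, predicted and sex-linked genes; 5 each way in other classes; 7 genes always; and up to 4 per list. Nos3, Cav1, Ldha and Gapdh were named besides, after their values were seen. Some genes that the rule takes are not reported here. The 5-UMI bound for S-phase cells was also set after the data were seen. Gene positions come from GENCODE vM21 on GRCm38, which held 27722 of the gene identifiers.

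The ratio, interval and list steps were tested on simulated data, and the clustering and naming were not. Both simulated libraries were drawn as Poisson counts from the control profile, which is what the intervals assume. Coverage near 95% thus checks the computation only. Spread between cells, embryos or libraries was not simulated. The true ratio is the set fold times the shift of the totals. In simulated counts of 13277 genes in all cells, with genes changed by 1.5-fold, 2-fold and 4-fold, intervals held the true ratio for 97.0% of the changed genes at each size and for 95.6% of the unchanged ones. Intervals of 13.1% of the unchanged genes excluded 1, since the changed genes also shift the totals that every gene is divided by. A raised list of genes lay at percentile 100, and 6% of unchanged lists lay outside the central 95% of random lists.

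Alternatives were scalings by TMM (edgeR 4.0.16) and median-of-ratios factors (DESeq2 1.42.0, R 4.3.3), totals without mitochondrial, ribosomal and hemoglobin genes, equal weight for each cell, cells with at least 2000 UMIs, 1000 genes and under 10% mitochondrial UMIs, cells thinned to 2500 UMIs, cells under 1% hemoglobin, cells with low cycle scores, equal class weights, minimums of 5 and 100 UMIs, list floors of 1 UMI and 50 CPM, 50 bins, the mean of a list, other clusterings, another denominator and unthinned shares. Further ones were chosen after seeing the data: control cells with Xist and no Y-linked UMI, the deepest cells left out, the unnamed clusters added, and classes from the other resolutions for ratios.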

Results

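Single-cell RNA was profiled from sorted vascular cells of mouse embryos to compare the endothelium of controls with endothelium of a genotype meant to delete Mekk3. Mekk3 is the protein of Map3k3, a kinase that acts upstream of the transcription factors Klf2 and Klf4 in endothelial cells. Tie2Cre, a recombinase driven in endothelial and blood cells, is meant to delete the floxed allele. The embryonic stage is one at which some arterial endothelial cells turn into blood progenitors, the transition the study was designed around. There was 1 control library (genotypes fl/fl and fl/+) and 1 mutant library (fl/-; Tie2Cre+), each from the dorsal aorta with the umbilical and vitelline arteries. Cells had been sorted as Ter119-, CD41 low or negative, CD31+, CD144+ and ESAM+. The control library held 6675 cells and 60790367 unique molecular identifiers (UMIs), with a median of 7566 per cell. The mutant library held 3242 cells and 21512713 UMIs, with a median of 5647 per cell. With 1 library per group no test was possible and no difference below has a replicate check. All intervals are exact 95% intervals that cover counting error only. The stage labels also differ: both titles give embryonic day 9.5, while the stage label of the mutant gives 9.7. The labels do not say how many embryos were pooled.

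Map3k3 RNA was not lower in the mutant library. In endothelial-like cells Map3k3 stood at 9.33 CPM (526 UMIs, scaled to the class total) in the control and 10.5 CPM (205 UMIs) in the mutant, a ratio of 1.13 with an interval of 0.956 to 1.33. The gene (ENSMUSG00000020700) lies on chromosome 11 from 106084613 to 106155446 on the plus strand of GRCm38. The 3′ tags counted here need not fall in the deleted exons, so this value checks neither the deletion nor the labels.

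Endothelial-like cells made up most of both libraries, and hematopoietic-like cells were scarcer in the mutant. Endothelial-like cells were 6116 of 6675 control cells (91.6%, interval 90.9 to 92.3) and 2821 of 3242 mutant cells (87.0%, 85.8 to 88.2). Hematopoietic-like cells, called from markers such as the blood transcription factors Spi1 and Myb and the cytoskeletal gene Coro1a, were 150 control cells (2.25%, 1.91 to 2.63) and 11 mutant cells (0.339%, 0.169 to 0.606). All were in cluster 15, whose leading genes also held the macrophage markers Fcer1g, Tyrobp and Lyz2. Its share thus does not separate blood progenitors from more mature blood cells. Mesenchyme-like cells, called from markers such as Twist1, Col1a1 and Col3a1, were 160 control cells (2.40%, 2.04 to 2.79) and 62 mutant cells (1.91%, 1.47 to 2.44), all in cluster 13, whose leading genes also held the neural marker Tubb3. The unnamed cells were 249 control cells (3.73%, 3.29 to 4.21) and 348 mutant cells (10.7%, 9.69 to 11.9). The sort gate selects for endothelium and against CD41-bright blood cells, so it can set these shares; the mutant cells were also shallower, with the medians above. Cluster 13 was a mix: at resolution 1.5 its cells parted into mesenchyme-like ones (80 control and 18 mutant cells, 1.20% and 0.555% of the libraries) and neural-like ones (80 control and 44 mutant cells), so most of its mutant cells were neural-like. With a few cells of other clusters, the neural-like class of that resolution held 90 control cells (1.35%) and 45 mutant cells (1.39%).

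Genes of the hypoxia and glycolysis list were higher in the mutant endothelial-like cells throughout. All 22 measured members had a higher CPM in the mutant, with a median log2 ratio of 2.06, at percentile 100 among 10000 random lists matched on expression, as a description of these libraries. Slc2a3, a glucose transporter, stood at 2.98 CPM in the control and 226 CPM in the mutant, a ratio of 75.7 (64.9 to 88.9). Bnip3, a mitophagy receptor induced by low oxygen, stood at 18.3 and 296 CPM, a ratio of 16.2 (15.2 to 17.3). Ndrg1 had a ratio of 14.2 (11.9 to 17.0) and Adm, which encodes the vascular peptide adrenomedullin, 12.7 (11.7 to 13.9). The glycolytic enzyme genes Ldha and Gapdh had ratios of 2.34 (2.31 to 2.37) and 2.31 (2.29 to 2.34). Several glycolytic enzymes have processed pseudogenes, so their levels are uncertain where the counting split reads between copies. The control endothelial-like cells were held by clusters 1, 3, 4, 6, 7, 10, 11 and 12 and the mutant ones by clusters 2, 5 and 8, so that nearly every such cluster was of 1 library and may be that library, not a cell type.

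**Figure D1:**
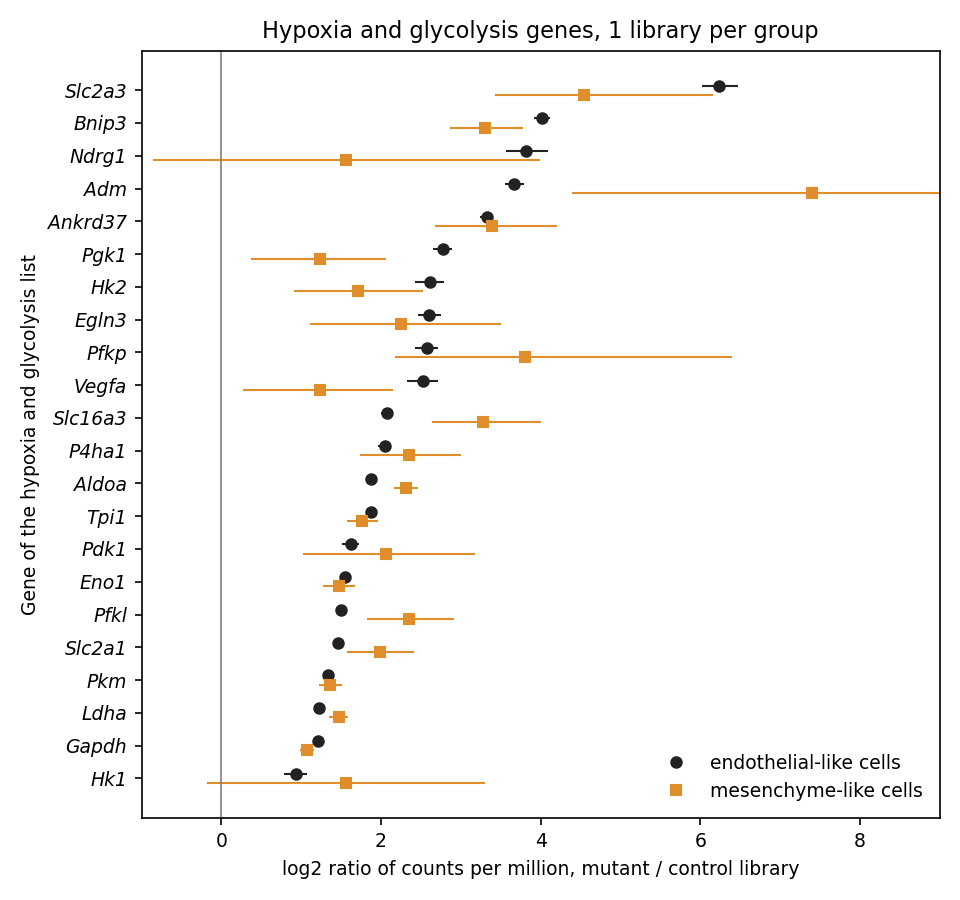
Each row is 1 gene of the hypoxia and glycolysis list; the horizontal axis is the log2 ratio of CPM in the mutant over the control library, circles stand for endothelial-like and squares for mesenchyme-like cells, and lines are exact 95% intervals for counting error. All 22 points of each class lie above 0, with medians of 2.06 and 2.02; Adm had 0 UMIs in control mesenchyme-like cells, so its point rests on the 0.5 UMI added and its line has no upper end.

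Klf2 and Klf4 were both lower in the mutant endothelial-like cells. Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656 on the plus strand), a transcription factor induced by blood flow, stood at 421 CPM (23765 UMIs) in the control and 122 CPM (2377 UMIs) in the mutant, a log2 ratio of -1.79 and a ratio of 0.290 (0.278 to 0.302). Klf4 stood at 55.7 and 27.2 CPM, a ratio of 0.489 (0.445 to 0.536). Of the 16 measured members of the list of flow and KLF2/4 responsive genes, 11 had a lower and 5 a higher CPM in the mutant. Its median log2 ratio was -0.85, below all random lists (percentile 0). With members limited to a mean of at least 50 CPM, the list median turned to 0.069. Slc9a3r2 had a ratio of 0.200 (0.180 to 0.221), the gap junction gene Gja4 0.222 (0.201 to 0.244) and Palmd 0.178 (0.125 to 0.247). Of the 6157 control UMIs of Gja4, 2364 lay in cluster 7 and 1776 in cluster 10. These 2 clusters held 898 control and 12 mutant cells, so the Gja4 ratio also carries the makeup of the libraries. With the unnamed clusters added, the log2 ratio of Gja4 went from -2.17 to -1.63. Nos3, the endothelial nitric oxide synthase, had a ratio of 0.319 (0.267 to 0.377). Against the direction of the list median, Cav1, a caveolar coat gene, had a ratio of 3.10 (2.90 to 3.31). The MEKK3 pathway list had a median log2 ratio of -0.23 at percentile 36.1; among its 13 members, Heg1 had a ratio of 0.483 (0.422 to 0.550) and Rasip1 0.702 (0.662 to 0.745).

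**Figure D2:**
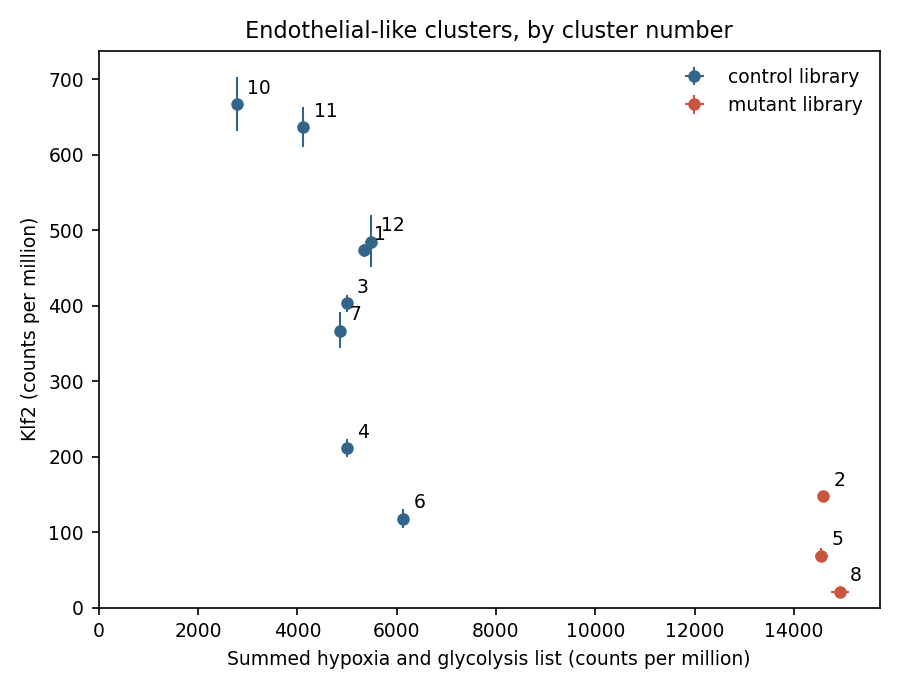
Each point is 1 endothelial-like cluster with at least 50 cells from the library shown by its color; the horizontal axis is the summed CPM of the hypoxia and glycolysis list, the vertical axis is the CPM of Klf2, and bars are exact 95% Poisson intervals. The list sums to between 14552 and 14922 CPM in the mutant clusters and to at most 6130 CPM in the control clusters, while Klf2 in control cluster 6 (118 CPM) lies below that in mutant cluster 2 (148 CPM).

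Genes of the arterial and hematopoietic programs differed in both directions. Gja5, a gap junction gene of arterial endothelium, stood at 30.5 CPM in the control and 1.95 CPM in the mutant, a log2 ratio of -3.95 and a ratio of 0.0640 (0.0451 to 0.0881). Gja5 was also among the leading genes of clusters 7 and 10, which held 898 control and 12 mutant cells and 1656 of the 1722 control UMIs of Gja5. Mutant cluster 5 stood near control cluster 7 in Dll4 (116 and 108 CPM) but below it in Gja4 (101 and 921 CPM) and Gja5 (8.40 CPM, 5.58 to 12.1, and 244 CPM, 226 to 264). The 12 mutant cells within clusters 7 and 10 stood at 392 CPM of Gja5 (144 to 852, from 6 UMIs) against 360 CPM in the control (343 to 377), and the other endothelial-like clusters at 1.65 CPM (1.13 to 2.32) against 1.27 CPM (0.986 to 1.62). Fewer arterial cells and a lower level within them were not separated, since Gja5 helps to define these clusters. Unnamed cluster 14, in which 213 mutant cells stood at 37.4 CPM, was outside this class, and with the unnamed clusters added the log2 ratio of Gja5 was -2.89; in cells with low cycle scores it was -4.95. The Notch pathway list had a median log2 ratio of -0.0016 at percentile 80.9 over 13 members (-0.81 in cells with low cycle scores), with Dll4, a Notch ligand of arteries, at a ratio of 1.81 (1.64 to 1.99), which turned to a log2 ratio of -0.063 in cells with low cycle scores, and Dtx3 at 2.13 (1.87 to 2.41). Gata2, a transcription factor of blood formation, stood at 13.6 and 6.99 CPM, a ratio of 0.513 (0.424 to 0.616). Runx1, which is required for blood cells to emerge from endothelium, stood at 1.49 and 2.26 CPM, a ratio of 1.52 (1.03 to 2.21) from 84 and 44 UMIs. With the unnamed clusters added its log2 ratio went from 0.61 to 1.02. Gfi1 had 10 UMIs in the control and 0 in the mutant, where a count of 0 allows 0.154 CPM, so a difference was not detectable at this depth; with the unnamed clusters added its log2 ratio went from -2.86 to 2.54. The hematopoietic stem cell program list had a median log2 ratio of -0.22 at percentile 33.9, with Procr at a ratio of 0.361 (0.287 to 0.449) and Meis1 at 2.44 (2.001 to 2.98). The log2 ratio of Procr went from -1.46 to -0.49 with the unnamed clusters added and to -2.08 in cells with low cycle scores, and that of Meis1 turned from 1.29 to -0.19 in cells with low cycle scores.

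Among the genes chosen by size in endothelial-like cells, the 12 highest in the mutant were Ndufa4l2, Slc2a3, Chchd10, Sox9, Selenbp1, Bnip3, Tnfrsf9, Vldlr, Ndrg1, Adm, Ankrd37 and P4ha2. Ndufa4l2, a mitochondrial gene induced by low oxygen, stood at 0.621 and 86.7 CPM, a ratio of 140 (100.03 to 201). Chchd10 had a ratio of 20.7 (17.3 to 24.9), the transcription factor gene Sox9 20.5 (17.1 to 24.8) and Selenbp1 18.5 (15.8 to 21.7). Those lowest in the mutant included Stmn2, Msmo1, Idi1, Slc9a3r2, Pinx1, Gja4, Rrm2, Rexo2, Hmgcs1, Hsph1 and Cycs. Stmn2, a regulator of microtubules, stood at 103 and 2.52 CPM, a ratio of 0.0245 (0.0181 to 0.0324). It was among the leading genes of cluster 7, which held 543 control and 9 mutant cells. Its ratio can thus also carry the makeup of the libraries. Msmo1, Idi1 and Hmgcs1, enzymes of sterol synthesis, had ratios of 0.179 (0.158 to 0.202), 0.194 (0.172 to 0.219) and 0.232 (0.204 to 0.264). Cycs, cytochrome c, had a ratio of 0.268 (0.257 to 0.280). In cells with low cycle scores several log2 ratios given here moved by over 1.5-fold without turning: Ndufa4l2 from 7.11 to 5.51, Sox9 from 4.35 to 3.01, Ndrg1 from 3.82 to 4.71, Adm from 3.67 to 2.82, Gja4 from -2.17 to -3.18, Gata2 from -0.96 to -1.55, Heg1 from -1.05 to -1.80, Esm1 from 2.23 to 1.39, Ung from -1.54 to -0.42, Cdkn1a from 1.76 to 1.08 and Sdf2l1 from -1.17 to -0.52. Stmn2 went from -5.34 to -6.92 in thinned cells.

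S-phase genes were lower in the mutant endothelial-like cells, while the G2/M list lay among random lists. The S-phase list had a median log2 ratio of -0.89 at percentile 0, with 19 of 20 members lower; Rrm2, a subunit of ribonucleotide reductase, had a ratio of 0.238 (0.221 to 0.257) and Ung 0.342 (0.293 to 0.399). The G2/M list had a median of -0.10 at percentile 69.7, with Ccna2 at 0.746 (0.704 to 0.790). Among cells with low cycle scores the S-phase median was -0.52. After thinning to 2500 UMIs, 35.1% of control (33.8 to 36.5) and 12.8% of mutant endothelial-like cells (11.4 to 14.3) held at least 5 UMIs of the S-phase list. Unthinned, these shares were 74.9% and 44.2%. The cut is one through a range, and 1752 thinned control cells held 4 to 6 such UMIs; free RNA, which can add to such counts, was not removed.

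Other fixed lists moved less or in mixed directions in endothelial-like cells. The stress and unfolded protein list had a median log2 ratio of 0.74 at percentile 99.99; Vldlr had a ratio of 13.5 (12.1 to 15.2) and Trib3 14.2 (11.1 to 18.4), while Sdf2l1, a chaperone partner, had 0.443 (0.409 to 0.480). This list median was -0.12 with members of at least 50 CPM. The angiogenic and tip cell list had a median of 0.36 at percentile 99.9, with Esm1 at a ratio of 4.70 (4.28 to 5.16) and Flt1 at 2.31 (2.24 to 2.37). The BMP and TGF-beta list had 0.17 at percentile 97.4 (-0.27 in cells with low cycle scores), with the receptor gene Acvrl1 at 3.20 (3.04 to 3.37) and its target Id1 at 0.510 (0.492 to 0.528). The interferon and inflammatory list had -0.05 at percentile 75.2, with H2-D1 at 0.348 (0.310 to 0.389) and Icam1 at 2.05 (1.91 to 2.21). The p53 target list had 0.05 at percentile 79.8 (0.90 with members of at least 50 CPM), with the cell-cycle inhibitor Cdkn1a at 3.39 (3.16 to 3.64) and Aen at 0.305 (0.261 to 0.355). The mesenchymal transition list had -0.10 at percentile 60.0. Its member Acta2 had a log2 ratio of -3.33, which turned to 1.93 with the unnamed clusters added. Of the 829 control UMIs of Acta2, 722 lay in control cluster 10, which stayed in the class while mutant cluster 14 did not. The cytoskeleton and junction list had -0.34 at percentile 15.8, and the developmental age list -0.13 at percentile 56.6 with Dlk1 at a ratio of 8.27 (7.11 to 9.64). The dissociation early gene list had -0.082 at percentile 72.9, with Ier3 at 5.62 (5.33 to 5.93) and Jun at 0.628 (0.603 to 0.654). The ribosomal protein list, fixed by symbol and so holding the kinase gene Rps6ka3, had 0.30 at percentile 100, and the mitochondrially encoded list -0.43 at percentile 3.15. The median of all genes was -0.14 on this scale, and -0.01 when mitochondrial, ribosomal and hemoglobin genes were left out of the totals. Several list medians near 0 changed sign under an alternative: Notch to 0.072 with TMM, interferon to 0.11 and G2/M to 0.030 with reduced totals, mesenchymal transition to 0.17 with members of at least 50 CPM, p53 to -0.093 in cells with low cycle scores, dissociation to 0.22 with the unnamed clusters added and developmental age to 0.094 as a mean.

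The sex-linked genes separated the libraries. Ddx3y, a gene of the Y chromosome, had 1023 UMIs in control and 0 in mutant endothelial-like cells, at least 118-fold lower against a floor of 3 UMIs over the group, with an exact interval of the ratio from 0 to 0.0105. Xist, expressed from an inactive X chromosome, stood at 427 and 999.7 CPM, a ratio of 2.34 (2.30 to 2.38), or a log2 ratio of 1.23. Against female control cells it was 0.21. These control cells were picked for holding a Xist UMI while all mutant cells were kept, so this fall follows in part from the choice. The list of 6 sex-linked genes had 3 measured members and a median log2 ratio of -9.44 at percentile 0, or -6.85 with the genes at 0 set to their bound.

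In mesenchyme-like cells, the mix of mesenchyme-like and neural-like cells named above (160 control and 62 mutant cells, 1251850 and 423792 UMIs, all in cluster 13) the hypoxia and glycolysis list was again higher, with a median log2 ratio of 2.02 at percentile 100 over 22 members. With the class taken from resolution 1.5, which left 80 control and 18 mutant cells, fewer than the 50 per library required elsewhere, the median was 2.18. The summed list rose in both parts of cluster 13, from 4803 to 14618 CPM in the mesenchyme-like and from 5750 to 15477 CPM in the neural-like cells. Other ratios of this class also carry the different makeup of the libraries. The 5 genes highest in the mutant by the fixed rule were Adm, Slc2a3, Actc1, Ddit4 and Ndufa4l2. Adm had 0 UMIs in the control and 28 in the mutant, at least 27.6-fold higher against a floor of 3 UMIs; the exact interval of the ratio, which also covers counting error in the 28 UMIs, begins at 21.0. Slc2a3 had a ratio of 25.1 (10.8 to 71.6), or a log2 ratio of 4.55 that was 3.25 at resolution 1.5, and Ddit4, a stress-induced inhibitor of mTORC1, 16.0 (9.12 to 29.8), or a log2 ratio of 3.96 that was 2.86 in thinned cells and 4.66 at resolution 1.5. The 5 lowest were Hes5, Rexo2, Hoxa7, Dnaja1 and Sfpq; Dnaja1, a chaperone gene, stood at 613 and 189 CPM, a ratio of 0.308 (0.241 to 0.388). The stress and unfolded protein list had a median of 1.10 at percentile 100 here, or -0.34 with members of at least 50 CPM. The flow and KLF2/4 list had -0.59 at percentile 3.88 (0.49 in cells with low cycle scores). The dissociation early gene list had -0.62 at percentile 0.25 here, with 12 of 14 members lower.

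Over all cells of each library, which mixes class makeup with level within a class, the hypoxia and glycolysis list had a median log2 ratio of 2.16 and the flow and KLF2/4 list -0.78, or 0.17 with members of at least 50 CPM.

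The shares of endothelial-like cells with a Klf2 or a Gja5 UMI were also lower in the mutant. Of cells thinned to 2500 UMIs (5216 control and 2191 mutant endothelial-like cells), 43.5% of control (42.2 to 44.9) and 16.6% of mutant cells (15.1 to 18.2) held a Klf2 UMI, against 60.7% and 28.4% unthinned. In mesenchyme-like cells, in which Klf2 stood at a lower level, the thinned shares were 15.6% (9.89 to 22.8) and 12% (4.53 to 24.3). Both intervals are wide and hold the mutant endothelial-like share, so these cells are too few to set a background for Klf2. For Gja5 the thinned shares were 5.08% (4.50 to 5.71) and 0.274% (0.101 to 0.595), against 10.2% and 0.815% unthinned. Gja5 was found in 0 of 135 thinned control and 0 of 50 thinned mutant mesenchyme-like cells, which should lack it, and in 4 of 160 and 0 of 62 unthinned; these cells are too few to set a background for the mutant share, since 0 of 50 allows up to 6%. Median depths before thinning were 9124 and 7679 UMIs in the endothelial-like and 7813 and 6242 UMIs in the mesenchyme-like cells. The venous transcription factor gene Nr2f2 had thinned shares of 20.3% (19.2 to 21.4) and 10.0% (8.77 to 11.3), against 44.6% and 22.2% unthinned, Klf4 8.99% (8.23 to 9.80) and 4.66% (3.81 to 5.62), against 25.0% and 12.3%, and Gata2 3.14% (2.69 to 3.65) and 1.60% (1.12 to 2.21), against 11.3% and 4.40%. The intervals overlapped for Map3k3, at 2.26% (1.88 to 2.70) and 2.65% (2.02 to 3.41), against 7.91% and 6.63% unthinned, and for Runx1, at 0.403% (0.249 to 0.615) and 0.639% (0.350 to 1.07), against 1.26% and 1.49%. Gfi1 was found in 4 thinned control and 0 mutant cells, Myb in 2 and 0, and Ptprc, the CD45 gene of blood cells, in none of either library, which allows shares of up to 0.0575% and 0.137%. Unthinned, these genes were found in 8, 17 and 1 control cells and in no mutant cells. At least 5 UMIs of the G2/M list were held by 56.0% (54.6 to 57.4) and 46.2% (44.1 to 48.3) of thinned cells, against 73.9% and 59.7% unthinned. Over whole libraries, thinning left out 1084 control and 807 mutant cells with fewer UMIs.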

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

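The alternatives with female control cells, without the deepest cells, with the unnamed clusters and with classes from other resolutions were chosen after seeing the data. Klf2 in endothelial-like cells stayed lower under all 15 alternatives (log2 -2.27 to -1.66): -1.71 with TMM, -1.72 with median-of-ratios, -1.66 with reduced totals, -1.99 with equal cell weights, -1.91 thinned, -2.27 in low-cycle cells and -1.89 against female control cells. Map3k3 ranged from 0.06 to 0.45, the highest with equal cell weights. The endothelial-like hypoxia list ranged from 1.88 (floor of 50 CPM) to 2.40 (mean), with 2.19 for reduced totals, 2.21 for equal cell weights and 2.16 in low-cycle cells; the mesenchyme-like one ranged from 1.72 to 2.43. The S-phase list stood at -0.76 with reduced totals, -0.74 with a floor of 50 CPM and -0.52 in low-cycle cells, which are chosen by these genes. The flow and KLF2/4 list stood at -1.42 in low-cycle cells and turned to 0.069 (0.17 over all cells) with a floor of 50 CPM. That floor also turned the stress list to -0.12 (-0.34 in mesenchyme-like cells) and the sex-linked list to 1.23 (0.63), since it leaves only Xist of the latter. Against female control cells the sex-linked list was 0.21, which follows in part from picking those cells by Xist. In low-cycle cells Dll4 turned to -0.063, Bbc3 to -0.093, H19 to -0.019 and Meis1 to -0.19; the cause was not tested. Acta2 turned to 1.93 with the unnamed clusters added, since cluster 14 expresses it. The endothelial-like share turned to 2.01 percentage points higher in the mutant with only endothelial and hematopoietic cells counted, a denominator that holds nothing else but the scarcer hematopoietic cells. The hematopoietic-like difference ranged from -2.27 to -1.91 percentage points. Over all named genes, 263 alternative values left the counting interval without turning a called direction, 1248 stayed inside it and 5 turned one; among the 263, 1 changed sign, that of Gfi1, to 2.54 with the unnamed clusters added. For a list, the counting interval runs from the median of its members' lower bounds to the median of their upper bounds. It is not an exact interval of the list median. List medians inside the central 95% of random lists left their counting interval with a changed sign in 18 alternative values, among them BMP and TGF-beta at -0.27 in low-cycle cells. Depth limits genes with few UMIs, among them Runx1, Gfi1, Myb and Ptprc.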

Other observations

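The tests of the early response list, of the mesenchyme-like cells, of free endothelial RNA, of clustering choices and of Klf2 and the hypoxia list within shared clusters were chosen after the results they measure had been seen. So were the sterol and nucleolar lists and the comparison with female control cells. Cluster 14, unnamed and made of 213 mutant and 0 control cells, held RNA of some arterial and blood-forming genes and none of others; these genes were chosen after their values were seen, and a cluster of 1 library need not be a cell type. Gfi1 stood at 17.5 CPM (22 UMIs, interval 10.96 to 26.5) there, against 3.93 CPM (8 UMIs, 1.70 to 7.74) in the arterial control cluster 10. Hlf stood at 11.9 CPM (6.67 to 19.7) against 1.96 CPM (0.535 to 5.03). Kit, at 96.2 CPM (79.8 to 115) in cluster 14, was about as high in mutant cluster 5 (107 CPM, 96.0 to 119). Myb and Ptprc had 0 UMIs in cluster 14, which allows up to 2.93 CPM by the exact Poisson interval, not by the floor of 3 UMIs. Runx1 stood at 14.3 CPM (8.48 to 22.6) against 9.82 CPM (6.00 to 15.2), with overlapping intervals. Gja5 stood at 37.4 CPM (27.5 to 49.7) against 505 CPM (475 to 537), and Klf2 at 161 CPM (140 to 185) against 667 CPM (632 to 703). So the mutant library was not without cells holding Gfi1 RNA, although its endothelial-like class had none.

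The rise of hypoxia and glycolysis genes in the mutant endothelial-like cells was not removed by any correction tried for it. The list median was at least 2.13 under 3 other scalings and 2.02 against female control cells. It was 2.04 as the lower of the values from thinned and filtered cells. These values argue against scaling, embryo sex and depth as the whole cause. Among clusters with at least 50 cells of the library, the lowest mutant cluster held 2.37 times the list RNA of the highest control cluster. That comparison cannot decide on a mixture of vascular beds, since genes of the list were not left out of the clustering. Bnip3, Ankrd37 and Pgk1 were among the leading genes of mutant cluster 2. In clusters 1, 4 and 6, which both libraries shared, the list was higher in the mutant cells. It summed to 11131 against 5333 CPM in cluster 1, 11196 against 4991 CPM in cluster 4 and 13039 against 6130 CPM in cluster 6. These values argue against a mixture as the whole cause only for the 93 mutant cells of these clusters. For the other mutant cells, of 2821 endothelial-like ones, a mixture stays open. The mesenchyme-like cells, a mix with neural-like ones, also rose (median 2.02), and endothelial RNA in them is argued against by the size of their excess, 94.5% of that in endothelial-like cells where endothelial markers reached 9.98%; the sort gate should have removed such cells and their lineage was not measured, so a change in Tie2Cre-targeted cells alone stays open. Handling before lysis cannot be told apart from genotype with 1 library per group, and the early response list (median -0.082, and -0.62 in mesenchyme-like cells) does not measure oxygen. A low-oxygen response of whole mutant embryos, for instance through poor circulation, is a hypothesis that stays open beside handling and the stage label. The labels also give a minus allele and Tie2Cre for the mutant only. Neither can be told apart from the other differences between the libraries.

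For lower Klf2 in the mutant endothelial-like cells, a dissociation response is argued against by the early response list (median -0.082 against -1.79 for Klf2, although it was -0.62 in mesenchyme-like cells), embryo sex by a log2 ratio of -1.89 against female control cells, and scaling by a ratio of at most -1.66. A mixture of vascular beds as the whole cause is argued against only for the 93 mutant cells in clusters 1, 4 and 6. These 93 cells held 0.315 times the Klf2 UMIs expected from control cells of the same clusters (0.210 to 0.456, 28 against 88.8 UMIs). They are 93 of 2821 mutant endothelial-like cells, too few to speak for the others. With cluster 8 added the value was 0.721 (0.555 to 0.921), which decides nothing. The 25 control cells of cluster 8 held no Klf2 UMI, so 0 was expected there, although that count allows up to 16.7 CPM. For the other mutant cells a mixture stays open as a cause, and for the 93 cells as part of it. Klf2 in the highest mutant cluster was 1.251 times that in the lowest control cluster of at least 50 cells (148 CPM in cluster 2 and 118 CPM in cluster 6). Mutant clusters 5 and 8 (69.3 and 21.3 CPM) lay below that control cluster. Cluster 8 had the lowest endothelial marker level of the class, 0.549 of the median cluster and near the bound of 1/2. The endothelial marker Cdh5 stood at 112 CPM in its mutant cells, against 165 CPM in the control cells of cluster 6. In the 25 control cells of cluster 8 it stood at 13.6 CPM from 3 UMIs. So the low Klf2 of cluster 8 comes with low endothelial markers. Loss of Mekk3, which the design names, may lower Klf2 within cells and was not tested apart from the stage label.

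The smaller share of hematopoietic-like cells in the mutant library was not removed by depth. Among cells thinned to 2500 UMIs, 0.698% of mutant cells (17 of 2435, interval 0.407 to 1.12) and 1.52% of control cells (85 of 5591, 1.22 to 1.88) held UMIs of 3 or more of the 17 fixed hematopoietic markers. A list of 10 of them, without 7 that other cells also express or that were judged less specific, had been counted first and gave 0.0411% and 0.483%. This count uses no clusters, so the ratio of 0.459 between these shares argues against clustering choices as well; the 3 resolutions held the same cells in this class and do not test them. The sort gate, the number of embryos and the stage stay open, as does an effect of the genotype, which may not be the only difference between the libraries.

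The lowest genes included enzymes of sterol synthesis and nucleolar proteins, which led to 2 hypotheses that these groups were lower as a whole. Members not among the extreme genes seen first were tested, to exclude that picking extreme genes made the pattern. The 13 other measured sterol genes had a median log2 ratio of -1.05 in endothelial-like cells, at percentile 0 of random lists, all 13 below 0. The 22 other nucleolar genes had a median of -0.62 at percentile 0.05, although Npm1 had a ratio of 1.16 (1.15 to 1.17). Lower sterol genes and lower nucleolar genes both remain hypotheses about these libraries and concern RNA levels, not synthesis of sterols or ribosomes. The ribosomal protein list was higher in mutant endothelial-like cells (0.30 at percentile 100). Lower RNA of sterol and nucleolar genes may go with the hypoxia list or with the difference in S-phase genes, which was not tested.

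The mutant library held 0 UMIs of 4 Y-linked genes in 3242 cells, which allows a share of cells with a UMI of up to 0.0925%, while 1680 of 6675 control cells (25.2%) held 1 or more. Genes of the X chromosome (275 genes) had a median log2 ratio of -0.11 in endothelial-like cells and autosomal genes (8234) -0.15.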
